A study of Mus musculus with 8 samples.

How the data were processed

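Total RNA had been extracted from epidermis peeled from the skin of newborn C57BL/6J mice, the inbred black laboratory strain, in 4 Zfp750 knockout and 4 wild-type samples. The epidermis had been separated by trypsin-EDTA overnight in the cold and snap-frozen, and ribosomal RNA was depleted before stranded paired-end libraries were made for an Illumina NextSeq, per the labels' protocols. Depletion, in place of poly(A) selection, keeps RNAs without a poly(A) tail, so abundant small nuclear and nucleolar RNAs take part of each library's total. The deposited table holds FPKM values (fragments per kilobase of transcript and per unit of mapped fragments), 1 value per gene symbol and library, made by the authors. The genome build was mm10, per the submitters' processing notes. The aligner, the quantification program, its annotation and whether it used strand are not given in the sources used here, so reads of overlapping genes on opposite strands may have been counted together.

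The table lists 15995 gene symbols. Each of them has a value in knockout 1, so a gene without a value in that library is not analysed here, and genes seen in the other libraries alone are missed. Of the listed genes, 2029 have no value in at least 1 other library. Their highest value over the libraries had a median of 0.167 FPKM, and a missing value was therefore taken as 0, a choice made after the values were seen. Krt1, Krt10, Flg2 and Rn45s are listed at exactly 0 in some libraries and at very high levels in others. A zero there can be a failed estimate, so these 4 genes were left out of the tests and are given per library.

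FPKM values carry no read counts, and no count model was used. At low levels the ratios between libraries gather at fixed steps, the mark of whole fragments. The position of the first step puts the depths of the libraries between that of knockout 1 and 1.45 times it. The absolute depth is unknown, so no counting interval is given for single values.

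Genes were tested where FPKM reached 1 in at least 4 of the 8 libraries, whatever their group, which left 11395 genes. In fits on fewer libraries the minimum was 3 of 7 or 2 of 4. These had first been run with 4 libraries whatever their number, which leaves out genes that are off in 1 genotype. The minimum was changed after it was seen that the Langerhans cell list went the other way under it. Values for fewer libraries are at the lower minimum unless stated. Since it changes the genes tested as well as the libraries, lists were also run at the 4-library minimum and with the 11395 genes of the full fit, and values are given where their calls differ. Values were transformed to log2(FPKM + 1), and the genotypes were compared with limma (version 3.58.1, in R 4.3.3) with a mean-variance trend and no other term. Fold changes are on that scale, which understates the change of genes with low values. Calls are at a Benjamini-Hochberg adjusted p of 0.05 over all genes tested. Log2 changes are given as knockout minus wild type with the standard error (SE), and levels as mean FPKM with SD. On simulated values for the same 11395 genes, 4 libraries against 4, with 200 genes changed, 11.0% of changes of 0.5 on the log2 scale, 62.7% of those of 1 and 89.7% of those of 2 were recovered, and 5.69% of calls were false (mean of 5 runs). The simulated noise was independent between genes and held no effect shared by libraries. These rates are therefore not the rates in the real data.

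The 34 gene lists, the test, the filter and most alternatives were chosen before the data were examined. Lists with at least 3 tested members (29) were compared with all other genes by limma's camera with a preset correlation between genes of 0.01, and again with a correlation estimated from the data, with Benjamini-Hochberg adjustment over the 29 lists. With 12 members an older symbol was used to find the gene. For each list the mean of its tested members per library, called its score, was also compared by a two-sided exact permutation test over the 70 assignments of 8 libraries to groups of 4. That test was added after the data were examined, and 0.0286 is the smallest p it can give.

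Named genes followed a fixed rule. It takes Zfp750, the 12 largest rises and 12 largest falls among called genes whose groups do not overlap, up to 4 members with the smallest p in each list, whether or not they passed, and a set of epidermal genes fixed by name. It lets any passing list member serve as an example, and 10 such examples (Cdsn, Casp14, Col17a1, Ccl20, Cxcl1, Krt6b, Sptlc1, Cers6, Acer3 and Klk8) were chosen after their values were seen. Tbcd, Epcam, Mfge8, Cd68, Cxcr6, Lyz2, Kit and the genes listed at 0 were chosen in the same way. Not every gene the rule named is given with its value in the text, and 2 of them are not reported here. Unnamed models, pseudogenes and small RNAs were counted but not named, unless a fixed list holds them. Coordinates are those of GRCm38, the same build as mm10, from the GENCODE annotation and, for the neighbours of Zfp750, the RefSeq gene table, in which 10570 tested genes matched by symbol.

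The sample titles carry a code, 11, 14 or 44, that the labels do not explain. They also carry a genotype number, which is not always the sample number used here. Knockouts 1 and 2 both have KO1 in their titles, while the other titles differ in this number within a genotype. What the shared KO1 means is not given. Each code occurs in both genotypes, with 1 sample each for 11 and 14 and 2 samples each for 44. Deviations from the genotype means, correlated across genes, moved together within each code, with r = 0.39 for code 11, 0.24 for code 14 and 0.43 for the means of code 44. These values are not independent, since deviations sum to 0 within a genotype. Samples of different codes were not compared, so a separate effect of each code is not shown. The code was therefore used as a replicate block in an alternative fit. The labels do not say that the samples of a genotype are separate animals, so p-values measure the spread between these samples. No pair of libraries held identical values, and the highest correlation between libraries was 0.982.

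Alternatives were other pseudocounts (0.1 and 0.5), other filters, 4 other scalings, limma without a trend, with robust estimation or with array weights, the block, each title code set alone, a fibroblast score as covariate, stricter thresholds, and leaving out each library. A melanocyte score or log2 Xist as covariate, and leaving out genes with missing values, were added after the data were examined. Figures were drawn with matplotlib 3.10.9.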

Results

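The transcriptome of newborn mouse epidermis was measured by RNA sequencing in 4 samples from Zfp750 knockout pups and 4 from wild-type pups. Zfp750 encodes a zinc finger protein of the differentiating epidermis, and the comparison addresses its part in skin lipid metabolism and in the barrier that the outer layers form. A value at or above 1 FPKM was present for 10637 to 11599 genes per library. The summed FPKM ranged from 483416 in wild type 3 to 577300 in knockout 2, and the 10 most abundant genes took 15.4% to 26.2% of it. The first principal component, 49.8% of the variance, placed all 4 knockouts on one side of all 4 wild types. The second, 23.9%, set knockout 4 apart from the other 7 libraries. Correlations between libraries were 0.915 to 0.982 within the knockouts, 0.959 to 0.981 within the wild types and 0.887 to 0.947 between genotypes.

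The level of Zfp750 itself matched the labels in each library. It stood at 2.68, 2.31, 2.29 and 1.53 FPKM in knockouts 1 to 4, against 119, 111, 81.6 and 93.7 FPKM in wild types 1 to 4. The change was -5.00 ± 0.16 (log2, SE; limma adjusted p = 4.49e-07). The gene lies on chromosome 11 from 121510978 to 121519333 (GRCm38), on the minus strand, and has 3 exons in its annotated transcript. It sits within the span of Tbcd on the opposite strand, and 1 of the 8 annotated Tbcd transcripts has an exon that overlaps it. Which part of the gene was removed is not given in the sources used here, and the low remaining level can include fragments of Tbcd if strand was not used in counting.

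Reads assigned to keratins that were nearly missing from wild type were abundant in the knockouts. Whether some of them came from related keratins was left open by the tests given below. Krt2, a type II keratin of upper epidermal layers at certain body sites, rose from 0.204 ± 0.110 FPKM (SD, n = 4) to 623 ± 268 (SD, n = 4), a log2 change of 8.90 ± 0.31 (SE; limma adjusted p = 5.26e-07). Krt8, a keratin typical of simple epithelia, rose from 1.71 ± 0.658 to 551 ± 138 FPKM (7.67 ± 0.22, limma adjusted p = 2.88e-07). Both lie in the type II keratin cluster of chromosome 15, Krt2 from 101810689 to 101818169 and Krt8 from 101996698 to 102004482, on the minus strand (GRCm38). The ratio of Krt8 to Krt2 was 1.41, 0.925, 0.743 and 0.811 in knockouts 1 to 4. Next came S100a9, a subunit of the inflammatory protein calprotectin, with a log2 change of 5.09 and the growth factor regulator Igfbp3 with 4.96. Epgn, a ligand of the EGF receptor, rose by 4.43 and Mt4, a metallothionein of stratified epithelia, by 4.35. Tchh, the trichohyalin of hair follicles and tongue, went from 26.5 ± 6.27 to 437 ± 151 FPKM (3.95 ± 0.27). Rab15 (3.92) and Rab11fip5 (3.74), both of membrane traffic, the lipoxygenase Alox8 (3.78), the peptide transporter Slc15a3 (3.74) and the other calprotectin subunit S100a8 (3.69) complete the 12 largest rises, all with limma adjusted p of 0.00202 or below. S100a9, at 189, 182, 49.1 and 34.1 FPKM in knockouts 1 to 4, Epgn and S100a8 were higher in knockouts 1 and 2 than in the others. Krt2, Krt8, Igfbp3, Mt4, Tchh, Rab11fip5 and Slc15a3 were higher in knockouts 3 and 4.

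Among genes with a standard symbol whose groups did not overlap, the 12 largest falls included Zfp750 and, next to it, Chga, the secretory granule protein chromogranin A, from 35.6 ± 14.3 to 1.23 ± 0.459 FPKM (log2 -3.99 ± 0.25, limma adjusted p = 1.57e-05). Krt12, known as the keratin of the cornea, went from 18.8 ± 5.68 to 0.454 ± 0.136 FPKM (-3.72 ± 0.23), and the peptide-processing enzyme Cpe from 84.4 ± 9.61 to 7.61 ± 1.67 (-3.32 ± 0.16). Slurp1, a secreted protein whose loss in humans thickens the skin of palms and soles, went from 68.7 ± 6.56 to 5.53 ± 2.76 FPKM (-3.50 ± 0.25). The protease inhibitors Serpina9 (-3.57) and Serpinb3a (-3.52) fell, as did Cyp11a1 (-3.26), the first enzyme of steroid hormone synthesis, which had 7.24 to 12.6 FPKM in the wild types and at most 0.174 in the knockouts. Ctss (-3.26), Sprr4 (-3.19), Endod1 (-3.15) and C1qc (-3.10) complete the 12. Serpinb3a and its neighbours are near-identical copies, so its value is uncertain where reads were shared.

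In all, 1785 of 11395 tested genes differed between the genotypes (limma, adjusted p under 0.05), 766 higher and 1019 lower in the knockouts, and 708 of them changed by at least 1 on the log2 scale. The groups did not overlap for 2426 tested genes, 21.3%, where chance gives 2.86%. Among called genes 93 were unnamed models or small RNAs, 33 of them higher. The count was 3669 with array weights, 1123 without wild type 1 and 1141 with log2 Xist as a covariate. Without knockout 2, knockout 3, wild type 1 or wild type 2, respectively, 505, 479, 474 and 474 genes were higher, and without wild type 1, 649 were lower. Xist, the RNA of the inactive X chromosome, stood at 126, 84.6, 150.4 and 1.84 FPKM in knockouts 1 to 4 and at 0.0223, 0.00870, 118 and 0.00825 in wild types 1 to 4. By this mark alone, female samples were unevenly spread over the genotypes. Knockout 4 lay between the high and the low libraries, and no Y-linked gene was tested.

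**Figure D1:**
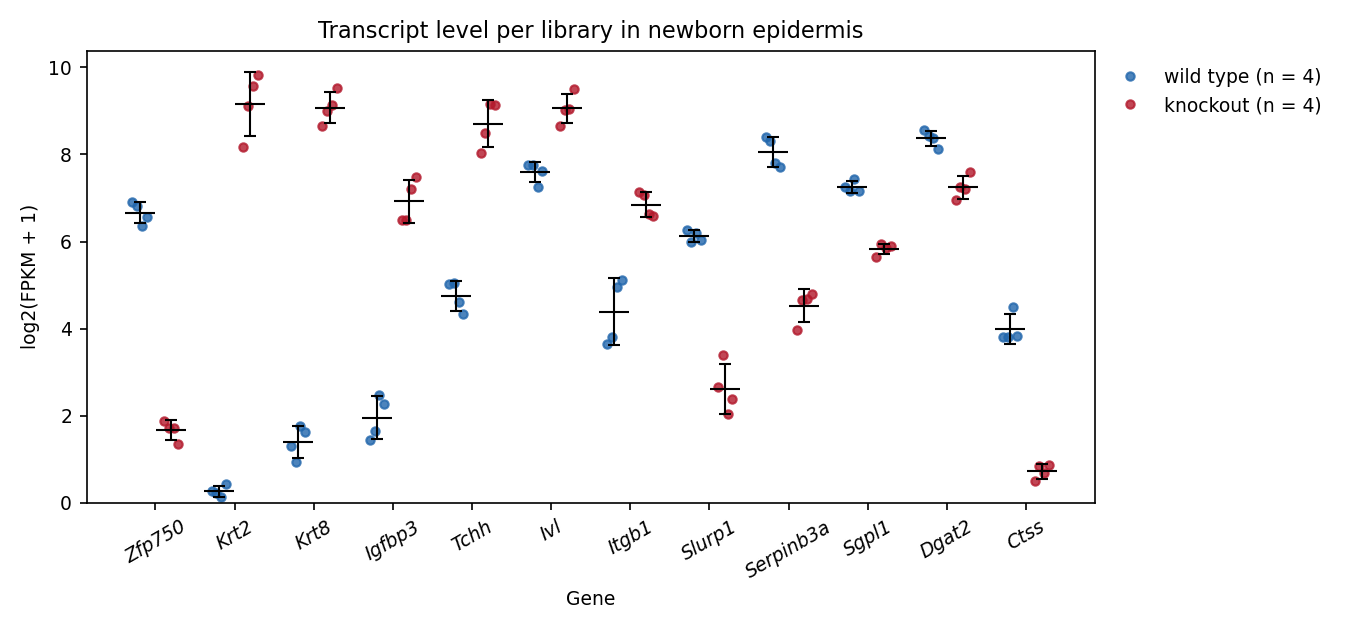
Level of 12 named genes per library on the log2(FPKM + 1) scale, with 4 wild-type (blue) and 4 knockout (red) libraries per gene; bars give the mean and SD. Zfp750 drops from 81.6 FPKM or more to 2.68 or less, Krt2 and Krt8 go the other way, and the 2 groups of points do not overlap for any gene shown.

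Genes of the cornified layer, the dead outer sheet of the skin, moved in both directions. Of 29 tested genes of the cornified envelope and terminal differentiation, 3 rose, 7 fell and 19 did not pass (4 and 8 adjusted over the list alone). Ivl, the envelope precursor involucrin, rose from 195 ± 29.98 to 543 ± 132 FPKM (log2 1.46 ± 0.19), while the cross-linking enzyme Tgm5 (-1.29 ± 0.14), the adhesion protein Cdsn (-1.17 ± 0.18) and the caspase Casp14 (-1.40 ± 0.25) fell. Lor, the most abundant envelope protein, stood at 2761 ± 557 FPKM in the knockouts and 3469 ± 348 in the wild types (limma adjusted p = 0.255). The list did not pass camera (adjusted p = 0.0709, and adjusted p = 0.749 with an estimated correlation), but did so without knockout 4 (0.00799) and without wild type 4 (0.00732). Of 20 late cornified envelope (Lce) genes, 9 fell and none rose (0 and 10 adjusted over the list alone). The 9 were all Lce1 members. Those with the smallest p were Lce1m, from 3291 ± 593 to 1264 ± 227 FPKM (-1.38 ± 0.18), Lce1h (-1.81) and Lce1i (-1.80). Lce1 genes share sequence, so single members are uncertain. Camera gave an adjusted p = 1.12e-04 for the Lce list, and an adjusted p = 0.675 with an estimated correlation.

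Of 12 small proline-rich (Sprr) genes, envelope components often induced by injury, Sprr1b (2.45 ± 0.50), Sprr2d (2.58 ± 0.47) and Sprr2k (1.92 ± 0.46) rose and Sprr4 fell (9 rose and 1 fell adjusted over the list alone). The Sprr2 copies are closely related and uncertain as single genes. The camera adjusted p of this list was 0.00626, and the adjusted p = 0.703 with an estimated correlation. The Sprr call was lost with title code 44 alone (0.170), against 8.60e-06 with codes 11 and 14 alone. Without knockout 1 or wild type 2 it was kept with the genes of the full fit (0.0399 and 0.00938) and at the 4-library minimum (0.0412 and 8.10e-04), and missed at the lower minimum (0.0868 and 0.0542). Among 5 tested suprabasal keratins Krt2 rose, and Krt78 (-2.12 ± 0.17) and Krt80 (-1.05 ± 0.17) fell, with Krt77 at -0.21 ± 0.34 (the same counts, 1 and 2, adjusted over the list alone; camera adjusted p = 0.535). Krt1 and Krt10, the main keratin pair of these layers, were listed at 0 in 6 libraries and had values in knockouts 1 and 2 alone, 12094 and 13833 FPKM for Krt1 and 11387 and 13519 FPKM for Krt10. Flg2, a filaggrin relative, was listed at 0 in the 4 wild types and at 389.7, 306, 292 and 433 FPKM in knockouts 1 to 4. No difference is drawn from these listings.

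Some of the genes that anchor basal keratinocytes to the basement membrane rose. Of 21 tested genes of the basal layer and hemidesmosomes, 10 rose, 0 fell and 11 did not pass (11 and 0 adjusted over the list alone; camera adjusted p = 2.19e-05, and adjusted p = 0.621 with an estimated correlation). The integrin subunits Itgb1 and Itgb4 rose from 22.2 ± 11.5 to 116 ± 23.1 FPKM (log2 2.46 ± 0.33) and from 19.2 ± 9.9998 to 76.9 ± 8.33 FPKM (2.09 ± 0.33). The desmosomal cadherin Dsg3 (1.97 ± 0.33) and the hemidesmosomal collagen Col17a1 (1.48 ± 0.33) rose as well. Krt14 rose by 1.46 ± 0.43 (limma adjusted p = 0.0464), while its partner Krt5 stood at 1304 ± 545 against 766 ± 396 FPKM (limma adjusted p = 0.302). With log2 Xist as a covariate 3 of the 21 genes passed. Libraries also differed within genotypes in this list: its score was 5.86 in knockout 4 against 6.54 to 6.83 in the other knockouts, and 4.90 and 5.16 in wild types 1 and 2 against 5.84 and 6.14 in wild types 3 and 4. The melanocyte score had the same low libraries, 1.19 in knockout 4, 1.06 in wild type 1 and 1.68 in wild type 2, against 2.23 to 2.74 in the other 5. Of 40 cell cycle genes, 0 passed limma's test at an adjusted p of 0.05 and 0 adjusted over the list alone. Those with the smallest p were the replication genes Mcm6 (0.66 ± 0.32), Pcna (0.51 ± 0.29), Mcm4 (0.64 ± 0.40) and Mcm3 (0.69 ± 0.43). The cell cycle list passed camera as higher (adjusted p = 0.0313), with adjusted p = 0.749 with an estimated correlation, and lost the call without knockout 1 (0.313), knockout 2 (0.143), wild type 1 (0.218) or wild type 2 (0.108). It also lost it with the fibroblast score as covariate (0.388).

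Of 36 genes of junctions and desmosomes 8 rose and 4 fell (10 and 4 adjusted over the list alone; camera adjusted p = 0.237). Cldn7, a tight junction claudin, rose from 0.390 ± 0.232 to 16.2 ± 3.96 FPKM (log2 3.62 ± 0.21), and Cldn23 fell from 74.8 ± 10.6 to 22.4 ± 2.81 (-1.69 ± 0.13). Among 47 epidermal transcription regulators, 6 rose, 1 fell and 40 did not pass (7 and 2 adjusted over the list alone; camera adjusted p = 0.0410, and adjusted p = 0.565 with an estimated correlation). Elf3 (2.17 ± 0.19) and Notch1 (1.61 ± 0.23) rose and Rora fell (-0.64 ± 0.12). The camera call of the regulators was lost without knockout 4 (0.0766) or wild type 3 (0.0939). Without knockout 1 it depended on the genes tested (0.0543 at the lower minimum, 0.0486 with the genes of the full fit and 0.0361 at the 4-library minimum), as it did without wild type 2 (0.0451, 0.0399 and 0.0544) or wild type 4 (0.0473, 0.0447 and 0.0575). Klf4, a regulator of barrier formation that acts with Zfp750, stood at 445 ± 110.5 FPKM in the knockouts and 453 ± 74.6 in the wild types (limma adjusted p = 0.911).

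Genes of stressed and wounded keratinocytes included some of the strongest rises. Of 26 tested, 7 rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0828). Tslp, a cytokine of irritated skin, had 2.93 to 3.84 FPKM in the knockouts, 0.0776 in wild type 3 and no value in the other wild types (limma adjusted p = 1.84e-05). The chemokines Ccl20 (3.12 ± 0.50) and Cxcl1 (3.54 ± 0.90) and the wound keratin Krt6b (2.56 ± 0.55) rose. Both chemokines were higher in knockouts 1 and 2 than in knockouts 3 and 4, and Krt6b was highest in knockout 3. Cxcl1 stood at 78.0, 93.5, 15.2 and 2.54 FPKM in knockouts 1 to 4 and at most at 2.00 in wild types. Krt6a, at 63.6 ± 55.5 against 13.7 ± 13.4 FPKM, and Krt16, at 279 ± 201 against 138 ± 118, did not pass (limma adjusted p = 0.166 and 0.317). With title codes 11 and 14 alone the stress list passed camera as higher (adjusted p = 8.60e-06), and with code 44 alone it did not (0.839). On all 8 libraries its adjusted p = 0.732 with an estimated correlation, which was not run on fewer. The list also passed as higher without knockout 4 (0.0170) or wild type 1 (0.0171). Without knockout 3 or wild type 3 it depended on the genes tested (0.0235 and 0.0435 at the lower minimum, 0.0274 and 0.0704 with the genes of the full fit, and 0.0528 and 0.0703 at the 4-library minimum).

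Genes of several lipid pathways changed. Of 44 tested genes of ceramide synthesis and processing, 4 rose, 15 fell and 25 did not pass (4 and 17 adjusted over the list alone; camera adjusted p = 0.00334, and adjusted p = 0.621 with an estimated correlation). Sgpl1, the lyase that ends sphingolipid breakdown, fell from 152 ± 14.8 to 56.1 ± 4.72 FPKM (log2 -1.42 ± 0.11, limma adjusted p = 5.06e-05), and Smpd1, acid sphingomyelinase, from 167 ± 11.1 to 72.1 ± 10.6 (-1.21 ± 0.12). Kdsr (-0.90 ± 0.11) and Sptlc1 (-0.77 ± 0.13), of the first steps of sphingoid base synthesis, fell. The ceramide synthase Cers6 (0.97 ± 0.20) and the ceramidase Acer3 (1.13 ± 0.21) rose. Sptlc2, Cers3, Elovl4, Abca12 and Cyp4f39, genes of the synthesis and transport of barrier ceramides, did not pass, with log2 changes of -0.06, -0.31, -0.33, -0.21 and 0.27.

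Of 31 genes of fatty acid synthesis, elongation and desaturation, 3 rose and 11 fell (6 and 11 adjusted over the list alone). The elongase Elovl7 fell from 118 ± 13.6 to 38.4 ± 4.26 FPKM (log2 -1.60 ± 0.12), the acyl-CoA synthetase Acsl6 fell by 1.93 ± 0.25, and the desaturase Fads2 rose by 1.38 ± 0.23. The camera adjusted p was 0.0286, and the adjusted p = 0.675 with an estimated correlation. The camera call was lost without wild type 1 (0.0517) or wild type 2 (0.0675). Without knockout 1 it depended on the genes tested (0.0557 at the lower minimum, 0.0486 with the genes of the full fit and 0.0218 at the 4-library minimum). Of 28 triacylglycerol and lipid droplet genes, 6 fell and none rose, with the same counts adjusted over the list alone (camera adjusted p = 0.0168, and adjusted p = 0.565 with an estimated correlation). Without wild type 3 the adjusted p was 0.0471 at the lower minimum, 0.0538 with the genes of the full fit and 0.0360 at the 4-library minimum. The fallen genes included Dgat2, which makes triacylglycerol, from 332 ± 39.1 to 153 ± 28.8 FPKM (-1.13 ± 0.15), the droplet protein Fitm2 (-1.06 ± 0.13) and the lipase Lipk (-0.94 ± 0.14). Pnpla1, the transacylase of acylceramide synthesis, did not pass (-0.42 ± 0.15, limma adjusted p = 0.103).

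Of 27 genes of fatty acid oxidation and PPAR targets, 1 rose and 6 fell (2 and 11 adjusted over the list alone; camera adjusted p = 0.00129, and adjusted p = 0.511 with an estimated correlation). The peroxisomal oxidase Acox3 fell from 16.0002 ± 1.54 to 3.19 ± 0.637 FPKM (log2 -2.03 ± 0.15), Cpt1a, which brings fatty acids into mitochondria, by 1.63 ± 0.26, and the thioesterase Acot1 by 1.37 ± 0.15. Of 25 cholesterol synthesis genes 2 rose and 4 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.870). Hsd17b7 (-1.42 ± 0.17) was among those that fell. Of 23 phospholipases and lipoxygenases Alox8 rose and 5 fell (1 and 7 adjusted over the list alone; camera adjusted p = 0.237), led by Pla2g3 (-2.27 ± 0.16) and Alox12e (-1.80 ± 0.20). The lipoxygenases Alox12b, at 329 ± 26.6 against 279 ± 35.5 FPKM, and Aloxe3, at 58.9 ± 12.1 against 87.9 ± 20.8, did not pass (limma adjusted p = 0.248 and 0.0697).

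Among proteases and protease inhibitors of the barrier more genes fell than rose. Of 32 tested, 2 rose, 14 fell and 16 did not pass (4 and 14 adjusted over the list alone; camera adjusted p = 0.00426, and adjusted p = 0.675 with an estimated correlation). The whey acidic protein family member listed as 1100001G20Rik (Wfdc21) fell from 496 ± 75.5 to 24.7 ± 5.05 FPKM (log2 -4.28 ± 0.17, limma adjusted p = 1.23e-06). Spink5, the inhibitor that restrains shedding of the cornified layer, fell by 1.18 ± 0.19 and the kallikrein Klk8 by 1.05 ± 0.18. The kallikrein Klk6 rose from 9.86 ± 5.16 to 65.1 ± 9.41 FPKM (2.69 ± 0.26) and the cathepsin Ctsl from 131 ± 42.0 to 454 ± 53.6 (1.83 ± 0.20).

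**Figure D2:**
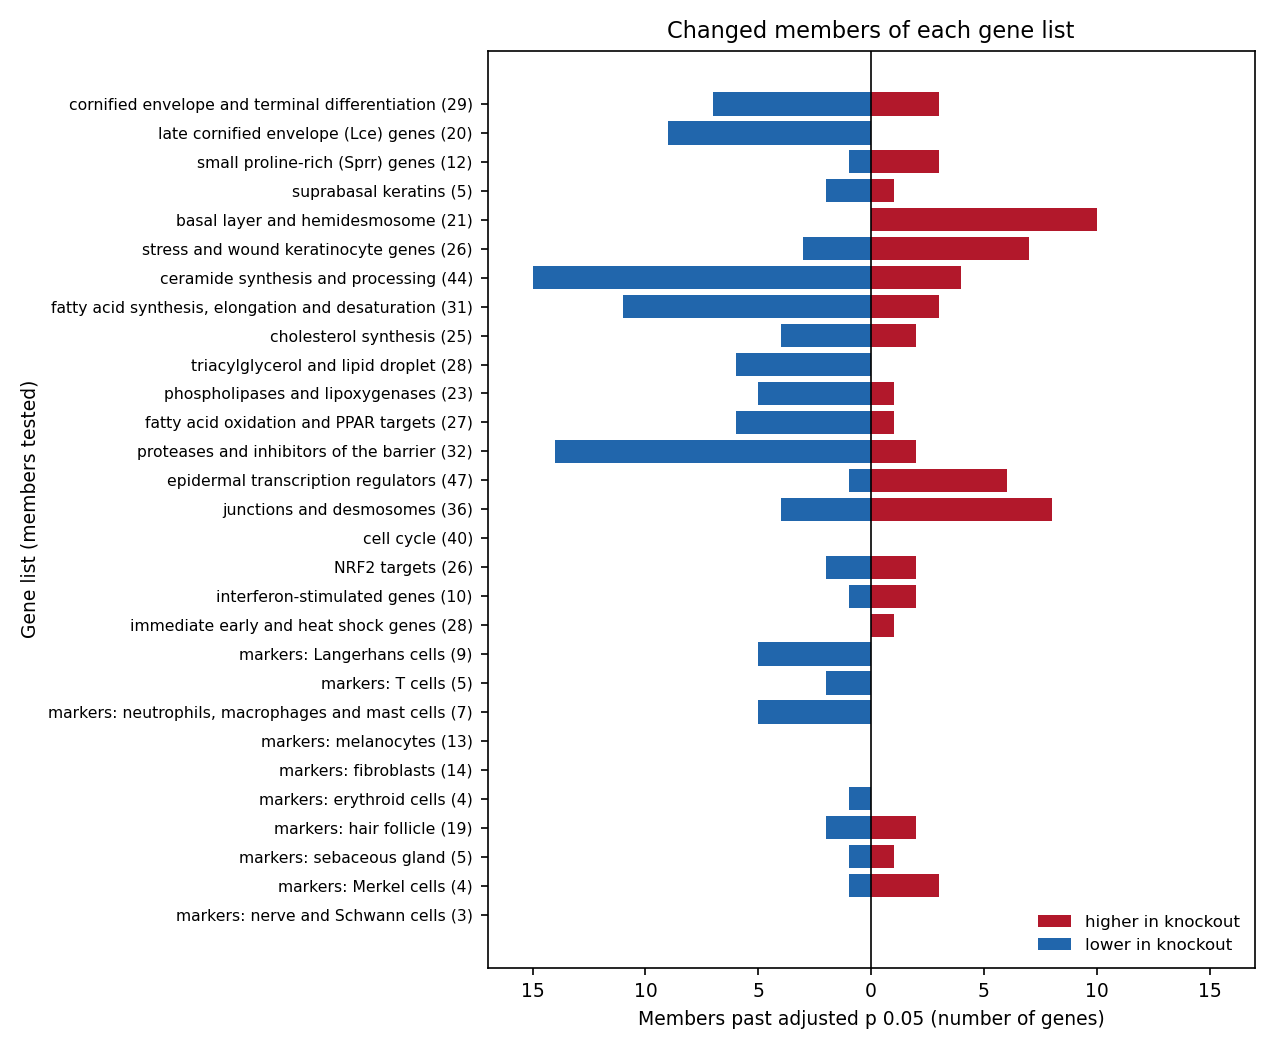
Number of genes past limma's adjusted p of 0.05 in each of the 29 gene lists with at least 3 tested members; bars to the right are genes higher in the knockouts and bars to the left genes lower, with the number tested in parentheses. Ceramide genes have the most falls (15), followed by barrier proteases and inhibitors (14), and the basal layer list has 10 rises and no falls.

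Of 21 tested markers of resident immune cells 12 fell in the knockouts. Of 9 tested markers of Langerhans cells, the antigen-presenting cells of the epidermis, 5 fell, of 5 markers of T cells 2 fell, and of 7 markers of neutrophils, macrophages and mast cells 5 fell, with 0 higher and the same counts adjusted over each list alone. The last 5 were C1qa, C1qb, C1qc, Emr1 and Lyz2, while Cd68 and Kit did not pass. The neutrophil markers Ly6g, Mpo, Elane, Retnlg and Cxcr2 were not tested, and Kit was the only tested mast cell marker. A fall of neutrophils or mast cells is therefore not shown. The T cell markers Thy1 (-0.65 ± 0.36) and Lck (-0.08 ± 0.21) did not pass. The cathepsin Ctss went from 15.2 ± 4.32 to 0.665 ± 0.194 FPKM (log2 -3.26 ± 0.19), the complement genes C1qa, C1qb and C1qc changed by -2.69, -2.95 and -3.10, and Tyrobp, Csf1r, the leukocyte antigen Ptprc and the T cell receptor component Cd3g by -2.83, -2.52, -1.48 and -1.28. Mean FPKM of the 12 fallen genes was 4.89 to 22.9 times higher in wild type. The camera adjusted p was 1.12e-04 for Langerhans cells, 0.0335 for T cells and 1.12e-04 for the third list. All 3 had an adjusted p = 0.511 with an estimated correlation, and the T cell call was lost without wild type 3 (0.0622). With the genes of the full fit it was also lost without knockout 4 (0.0510), and at the 4-library minimum, with 3 members left, without wild type 1 (0.573) or wild type 2 (0.515). Of the 21 genes in these lists, 1 is also in another list and 2, Epcam and Mfge8, had a mean of 5 FPKM or more in the knockouts.

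None of 13 melanocyte markers, 14 fibroblast markers or 3 nerve and Schwann cell markers passed limma's test or passed adjusted over the list alone, with median log2 changes of 0.34, 0.53 and 0.24 (camera adjusted p = 0.154, 0.158 and 0.870). The members with the smallest p included the pigment enzymes Tyrp1 (0.68 ± 0.41), Tyr (0.63 ± 0.51) and Dct (0.68 ± 0.60), the receptor Ednrb (0.50 ± 0.45), the matrix genes Col6a3 (1.22 ± 0.56), Col6a2 (0.85 ± 0.58), Col3a1 (0.94 ± 0.78) and Bgn (0.54 ± 0.31), and Sox10 (0.24 ± 0.33), Ncam1 (0.38 ± 0.40) and Mbp (-0.25 ± 0.18) of nerves. Camera called the melanocyte list higher without knockout 4 (0.00593), and without wild type 4 (0.0461) but not at the 4-library minimum there (0.0511), and called the fibroblast list higher without knockout 4 (0.0215). Over all 8 libraries both had an adjusted p = 0.749 with an estimated correlation. Of 19 hair follicle markers Tchh and Cux1 rose and Krt79 and Krt32 fell (the same counts, 2 and 2, adjusted over the list alone; camera adjusted p = 0.197). Of 5 sebaceous gland markers Mgst1 rose and Far2 fell and Soat1 stood at -0.21 ± 0.20 (2 and 1 adjusted over the list alone; camera adjusted p = 0.786). Of 4 erythroid markers Fech, also of general heme synthesis, fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.671), while the hemoglobin genes Hba-a2 (0.85 ± 0.91), Beta-s (0.61 ± 0.80) and Hba-a1 (-0.25 ± 0.73) did not pass. All 4 tested markers of Merkel cells, the touch cells of the skin, changed in limma's test: Krt8, Krt18 (1.89 ± 0.46) and Tubb3 (1.09 ± 0.14) rose and Chga fell (the same counts, 3 and 1, adjusted over the list alone). Camera gave an adjusted p = 0.0410 for this list, an adjusted p = 0.511 with an estimated correlation and 0.0630 with the title code as a block. The Merkel cell call was also lost without knockout 1 (0.0600), knockout 4 (0.0568), wild type 3 (0.0809) or wild type 4 (0.0869), and at the 4-library minimum, with 3 members left, without knockout 2 (0.112) or knockout 3 (0.0915). Among endothelial, adipocyte and skeletal muscle markers 1, 2 and 2 genes were tested and none passed over all genes (1 adipocyte marker, Fabp4 at 1.26 ± 0.42, higher and 1 muscle marker, Mylpf at -1.07 ± 0.38, lower adjusted over the list alone). The others were Egfl7 of endothelium (0.12 ± 0.31), Lipe (-0.15 ± 0.23) of adipocytes and Tnni2 (0.65 ± 0.41) of muscle. Of the sex-linked list Xist was the only gene tested (3.80 ± 1.74, limma adjusted p = 0.188), and mitochondrially encoded genes are not analysed here.

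**Figure D3:**
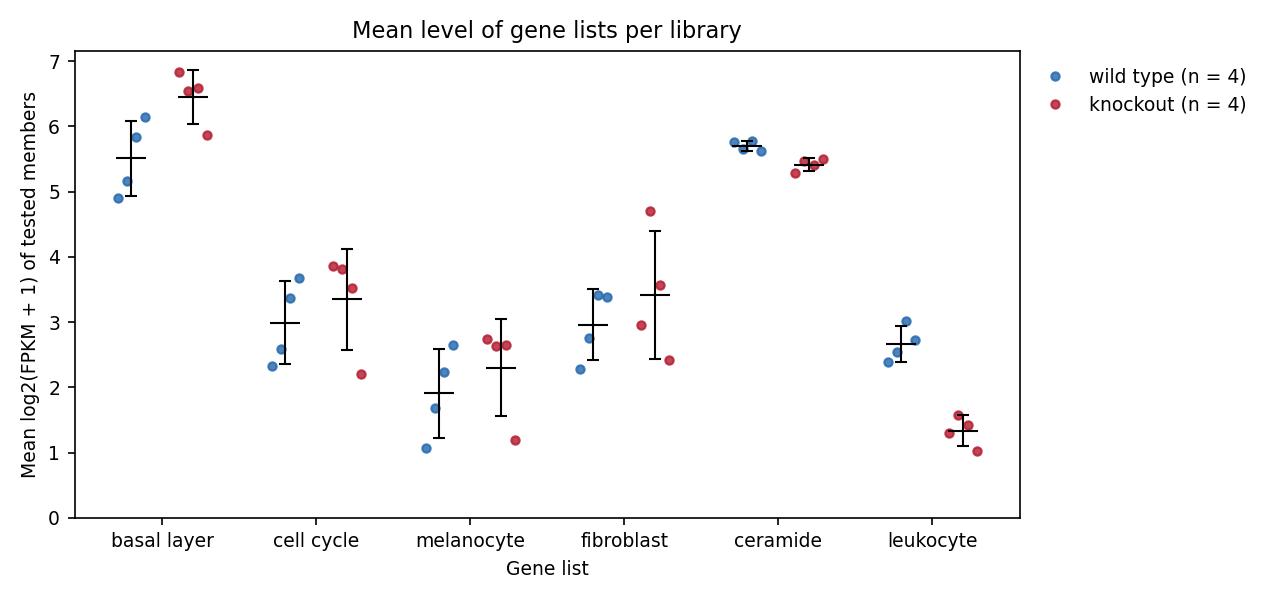
Mean log2(FPKM + 1) of the tested members of 6 lists in each library, with 4 wild-type (blue) and 4 knockout (red) libraries; bars give the mean and SD. The leukocyte score lies at 1.03 to 1.58 in the knockouts and 2.39 to 3.02 in the wild types, while the melanocyte and fibroblast scores overlap between genotypes.

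Other responses were small in number. Of 26 NRF2 targets Gsta3 and Mgst1 rose and Gsta4 and Txn1 fell (the same counts, 2 and 2, adjusted over the list alone; camera adjusted p = 0.786). Of 10 interferon-stimulated genes Ddx58 (log2 1.19 ± 0.18) and Isg15 (0.96 ± 0.22) rose and Irf7 fell (-1.52 ± 0.38), with 3 and 1 adjusted over the list alone (camera adjusted p = 0.595), and Cxcl10 stood at 1.58 ± 0.52 (limma adjusted p = 0.0701). Of 28 immediate early and heat shock genes Ier3 rose (2.38 ± 0.39), with the same count adjusted over the list alone (camera adjusted p = 0.0893). Myc (0.99 ± 0.31), Hsph1 (0.75 ± 0.24) and Junb (0.91 ± 0.31) did not pass. With codes 11 and 14 alone this list passed camera as higher (3.16e-04), and with code 44 alone it leaned lower without passing (0.149). It also passed as higher without knockout 3 (0.0235), wild type 1 (0.0287) or wild type 2 (0.0235), while over all 8 libraries its adjusted p = 0.732 with an estimated correlation. The median, the mean and the camera direction differed in sign for suprabasal keratins (median -0.21, mean 1.09, lower), erythroid markers (0.18, 0.12, lower), NRF2 targets (0.04, -0.01, higher), interferon-stimulated genes (-0.09, 0.15, higher) and sebaceous markers (-0.09, 0.03, higher).

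Across the 29 lists, 14 passed camera with the preset correlation and 0 of them with an estimated one, where the smallest adjusted p was 0.511. By the exact permutation test of the list scores, ceramide, fatty acid synthesis, triacylglycerol, fatty acid oxidation and barrier protease genes were lower, and transcription regulators and junctions higher, in each of the 4 knockouts than in each of the 4 wild types, each with the smallest possible p = 0.0286 and an adjusted p = 0.0690, which does not pass. The 3 immune cell lists, lower, and the Merkel cell and suprabasal keratin lists, higher, had the same values. Of the called suprabasal keratins only Krt2 was higher, the median change was -0.21 and the camera direction was lower. Their higher score is therefore not a rise of the list. Some lists called by camera had scores that did not part every knockout from every wild type. The Lce score (exact permutation p = 0.143, adjusted p = 0.230) was among them. So were the Sprr score (exact permutation p = 0.143, adjusted p = 0.230) and the cell cycle score (exact permutation p = 0.457, adjusted p = 0.576). With 2 samples per genotype in each title code set, the Lce, basal layer and fatty acid oxidation lists passed camera with code 44 alone and with codes 11 and 14 alone. The Langerhans cell and the neutrophil, macrophage and mast cell lists did so at the lower minimum and with the genes of the full fit. At the 4-library minimum, which keeps only genes at 1 FPKM or more in all 4 libraries, they had 4 and 3 members and did not pass with codes 11 and 14 (0.847 and 0.390), and they had too few to be tested with code 44. With code 44 alone the calls of transcription regulators (adjusted p = 0.0794), cell cycle (0.106) and Merkel cells (0.137) were lost. With codes 11 and 14 alone those of ceramide (0.0532), fatty acid synthesis (0.186), triacylglycerol (0.0543) and protease (0.0850) lists were lost. Those of transcription regulators (0.0532) and T cells (0.0514) were kept with the genes of the full fit (0.0455 for both), while T cells then lost theirs with code 44 (0.0884 against 0.0369). The basal layer score differed by 0.94 ± 0.36 (log2, SE; exact permutation p = 0.0571, adjusted p = 0.127). With the title code as a term the difference was 0.94 ± 0.23 (log2, SE), and within each code every knockout lay above every wild type. The exact permutation test within codes gave the smallest p that 24 assignments allow, 0.0833 (adjusted over 9 scores 0.250), and camera with the code as a block an adjusted p of 1.18e-07.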

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

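Of the tests in this part, the counts over other splits of the samples were planned, and those of yield, sex, title codes in the basal score, recovery of the lower layers and keratin reads were chosen after the results were seen. The bounds for the tests of sex in basal genes and of keratin reads were also revised after their values were known.

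Among groups of 4 libraries, 17 of 320 tested held a library far from the other 3, where chance gives about 16 (1 in 20). Most of them lay in knockout 4 or wild type 3, so a total near chance does not show that these libraries were like the others. In knockout 4 these were Pla2g3 at 2.39 FPKM, Cldn23 at 26.6, Mcm6 at 16.7, Gsta4 at 1.22, Xist at 1.84, Dct at 8.34, Ednrb at 1.08 and Aloxe3 at 76.9 FPKM, and the melanocyte score at 1.19 against 2.64 to 2.74. In wild type 3 they were Ctss at 21.7 FPKM, Tslp at 0.0776, Klk6 at 17.6, Xist at 118 and Cdsn at 799 FPKM. In knockout 3 they were Tgm5 at 12.01 and Cd3g at 0.967 FPKM, and in wild type 1 Gsta4 at 9.13 FPKM.

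Leukocyte transcripts were lower in each knockout than in each wild type, with a score difference of -1.33 ± 0.18 (log2, SE; exact permutation p = 0.0286, the smallest possible, and 0.129 adjusted over 9 scores). A lower yield of cells other than keratinocytes would bring melanocyte and fibroblast transcripts down alike, but relative to the leukocyte score these scores stood higher by 1.73 ± 0.38 and 1.79 ± 0.41. With log2 Xist as a covariate the difference was -1.6 ± 0.13, so the uneven sex of the pups, as far as Xist gives it, is not its whole cause. Fewer leukocytes in knockout epidermis may account for the pattern, as a hypothesis found in the same data. Of the 21 tested markers 12 fell, and the others did not pass. Among the latter, Cd68 stood at 4.71 FPKM in the knockouts and 4.38 in the wild types, and Cxcr6 at 2.17 and 2.16. A loss of all leukocytes alike is therefore not shown. Genes without a value in knockout 1 are not listed, so markers missing from that library could not be tested. Listed were 13 of 15 Langerhans cell markers, 10 of 18 T cell markers and 12 of 20 of neutrophils, macrophages and mast cells. Kit, among those that did not pass, is also in the melanocyte list. Uneven separation of immune cells alone from the tissue was not tested.

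Of 21 basal layer genes 10 rose, while the score difference of 0.94 ± 0.36 did not pass (exact permutation p = 0.0571, adjusted p = 0.171) and the camera call (adjusted p = 2.19e-05, and 1.18e-07 with the title code as a block) was lost in the fit without the block (adjusted p = 0.621 with an estimated correlation). Within title codes every knockout lay above its wild types, at 6.83 against 6.14 for code 11, 6.54 against 5.84 for code 14, and 6.58 and 5.86 against 4.90 and 5.16 for code 44, a difference of 0.94 ± 0.23 with the code as a term (exact permutation p within codes 0.0833, the smallest possible, and 0.250 adjusted over 9 scores). Uneven recovery of the lower epidermis could raise them, since melanocyte and cell cycle scores also varied between libraries of 1 genotype. With the melanocyte score as a covariate the difference was 0.68 ± 0.12, which stayed more than 2 SE above 0. That score may follow the recovery of the lower layers only in part, so recovery as the whole cause stays open. With log2 Xist as a covariate the basal score difference was 0.58 ± 0.39, within 2 SE of both 0 and 0.94, so the part of sex in these rises stays open.

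Krt2 and Krt8 rose from near 0, and Krt1, from the same gene cluster, had values in knockouts 1 and 2 alone. If reads of a failed Krt1 estimate had made up the rise of Krt2, it would have been missing where Krt1 had a value, but the lower Krt2 level of those 2 knockouts was 285 FPKM, and wild types, all with Krt1 listed at 0, had at most 0.355. Krt2 was higher, at 756 and 903 FPKM, in the knockouts with Krt1 listed at 0, so a part from Krt1 reads may remain there. Krt2 reads counted to Krt8 would have kept a fixed ratio, and the ratio of Krt8 to Krt2 varied by 1.90 times among the knockouts but by 1.24 times without knockout 1, so this stays open. Simple epithelium in the preparations would have brought Krt18, the partner of Krt8, which stood at 2.4% of Krt8 at most.

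Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, gave as many changed genes as the 1785 observed, and the highest of the others gave 2. That share is under 0.05, but it is the smallest that 35 splits allow, and most of them disregard the title codes. It makes chance less likely for the count without excluding it. Among the 12 splits that part each title code evenly, the highest of the others gave 0 genes, and 12 splits are too few for a share under 0.05. As many lists as the 14 that passed camera with the preset correlation were passed in 5 of the 35 splits, and the highest of the others passed 16. Chance is therefore not excluded for the number of lists called. Among the same 12 splits the real one alone passed as many lists, and the next passed 13.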

How the results depend on the processing

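The melanocyte and Xist covariates and the exclusion of genes with missing values were chosen after the results were seen, as was the minimum of libraries in fits on fewer of them. In all settings, genes called there and in the reported fit had the same direction. Zfp750 stayed called in each, with a log2 change of -5.09 to -4.89 when 1 library was left out. Of 4893 alternative values of list and gene tests, 4591 kept direction and side of the threshold, 156 lost a call, 79 gained one and 67 changed direction. Of 864 counts of genes or list members 63 were lower and 54 higher than reported by over 1.5 times, and of 777 list medians 17 moved by more than the spread and 3 changed sign. Of 4087 alternative values of 153 named genes, 96 lost the call and 36 changed direction, all of the latter for genes that did not pass. Of the 108 called named genes, 14 lost the call in at least 1 setting with all 8 libraries. The unknown sequencing depth limits low values. Except where fewer libraries or stricter thresholds explain it, the cause was not tested.

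With the title code as a replicate block, 2261 genes changed and the Merkel cell list lost its call (adjusted p = 0.0630).

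With array weights 3669 genes changed (1942 higher, 1727 lower). With log2 Xist as covariate there were 1141 (465 and 676), with a minimum change of 1 on the log2 scale 708 (315 and 393), and at an adjusted p of 0.01 838 (341 and 497). With code 44 alone 652 were higher and 575 lower, and with median-of-ratios scaling 840 and 867, where the reported fit had 766 and 1019. With 1 library left out 1123 to 2326 changed, 474 to 1083 higher and 649 to 1243 lower.

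The fatty acid synthesis list lost its camera call with an FPKM minimum of 5 (adjusted p = 0.0511), quantile normalization (0.0514), codes 11 and 14 alone (0.186), and the fibroblast (0.0762), melanocyte (0.0890) or Xist (0.469) covariate. With codes 11 and 14 alone, 2 libraries a group, so did ceramide (0.0532), triacylglycerol (0.0543) and protease (0.0850) genes. Array weights gave a call to the cornified envelope list (0.00918). With an estimated correlation no list was called, with 0.675 for Lce genes, fatty acid synthesis and proteases, 0.621 for ceramide, 0.565 for triacylglycerol and 0.511 for fatty acid oxidation genes. With 1 library left out the adjusted p was 0.00732 to 0.284 for cornified envelope, 1.58e-06 to 0.00145 for Lce, 0.000351 to 0.0184 for ceramide, 0.00648 to 0.0675 for fatty acid synthesis, 0.240 to 0.931 for cholesterol, 0.00642 to 0.0471 for triacylglycerol, 0.000656 to 0.00374 for fatty acid oxidation and 0.000493 to 0.0319 for protease genes.

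Other lists lost a call with an FPKM minimum of 5 (Sprr 0.130, transcription regulators 0.106, cell cycle 0.0599), quantile normalization (regulators 0.0502, T cells 0.0553, Merkel cells 0.0514), array weights (regulators 0.121, T cells 0.0702, Merkel cells 0.0893), median-of-ratios scaling (Merkel cells 0.0521), no filter (Merkel cells 0.734) and the fibroblast (0.388) or melanocyte (0.707) covariate (cell cycle). Calls as higher were gained by stress genes without a filter (0.0173), at a mean of 1 FPKM (0.0392) and with array weights (0.0409), by immediate early genes with the fibroblast (0.0240), melanocyte (0.0453) and Xist (0.00173) covariates, by junctions with the last 2 (0.0485 and 0.0123), and by melanocyte (0.00723), fibroblast (0.0122) and hair follicle (0.0407) lists with array weights.

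Lists that went the other way, all without a call there, are given by camera adjusted p. Cholesterol synthesis did so with codes 11 and 14 alone (0.272) and the fibroblast (0.578), melanocyte (0.399) and Xist (0.0665) covariates. Without a filter, interferon-stimulated (0.0838), erythroid (0.624), hair follicle (0.480) and sebaceous (0.810) lists did. Interferon-stimulated genes also did with an FPKM minimum of 5 (0.457) and array weights (0.837). With code 44 alone NRF2 targets (0.550) and immediate early genes (0.149) did, and with codes 11 and 14 alone erythroid (0.512) and sebaceous (0.851) markers. Nerve markers did with the fibroblast (0.819), melanocyte (0.816) and Xist (0.566) covariates, and cell cycle (0.588) and melanocyte (0.791) lists with Xist. The median of cell cycle genes became -0.035 with the melanocyte covariate and -0.23 with Xist, and that of Merkel cell markers -0.085 without a filter. With 1 library left out, cholesterol synthesis and 4 further lists changed direction in some fits, with an adjusted p of 0.664 to 0.984 for NRF2 targets, 0.368 to 0.893 for interferon-stimulated genes, 0.610 to 0.999 for sebaceous and 0.583 to 0.983 for nerve markers over all 8 fits.

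Genes that did not pass and went the other way had these log2 changes. Values were 0.084 for Hba-a1 with a pseudocount of 0.1. With array weights they were 0.17 for Krt77, 0.12 for Lck, 0.071 for Lipe, 0.011 for Klf4 and 0.013 for Sptlc2. With code 44 alone they were 0.05 for Lipe, -0.52 for Beta-s and 0.061 for Soat1. With codes 11 and 14 alone they were 0.020 for Krt77, 0.0082 for Lck, -0.12 for Sox10, 0.40 for Klf4 and 0.11 for Sptlc2. Egfl7 had -0.12, -0.14 and -0.31 with the fibroblast, melanocyte and Xist covariates, and Sox10 -0.017 and -0.30 with the last 2. With Xist as covariate Dct had -0.027, Ednrb -0.026, Tnni2 -0.021, Beta-s -0.10 and Ncam1 -0.028. Xist itself has no value there. With 1 library left out the ranges were -0.45 to 0.041 for Krt77, -0.17 to 0.11 for Lck, -0.058 to 0.40 for Egfl7, -0.27 to 0.097 for Lipe, -0.13 to 1.48 for Hba-a2, -0.18 to 1.18 for Beta-s, -0.67 to 0.45 for Hba-a1, -0.17 to 0.12 for Klf4 and -0.14 to 0.0016 for Sptlc2.

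In fits on fewer libraries, calls depended in part on the genes tested. At the 4-library minimum, 21 of 278 list results that could be tested both ways had another call than at the lower minimum, 11 losing and 10 gaining it, and 12 went the other way. With the genes of the full fit 10 of 289 did, 4 losing and 6 gaining. The largest were the Langerhans cell list with codes 11 and 14 alone (0.847 with 4 members against 8.01e-05 with 12) and the neutrophil, macrophage and mast cell list there (0.390 with 3 against 0.00190 with 8). At the 4-library minimum, which leaves out Krt2, under 1 FPKM in wild types, suprabasal keratins were called lower without knockout 1 (0.0170), knockout 2 (0.0151) or knockout 4 (0.0214) and with code 44 alone (0.0125), and phospholipases lower without knockout 4 (0.0280) and with code 44 (0.0392). With 1 library left out, 942 to 2191 genes changed at that minimum and 1094 to 2264 with the genes of the full fit.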

Other observations

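The tests of gene families, of the title code and of the neighbours of Zfp750 were chosen after the results were seen. The bounds of the last 2 were also revised after their values were known.

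Grouped by symbol, 118 families with at least 10 tested genes were compared with all other genes for the share called by limma, and 5 passed (Fisher's exact test, two-sided, adjusted over the families). That test takes genes as independent, although the estimated correlation between Lce genes was 0.684. Families were not matched to other genes by level or spread. Changes were more frequent among keratins, with 5 of 22 higher and 5 lower (adjusted p = 0.0270), namely Krt2, Krt8, Krt18, Krt6b and Krt14 as higher and Krt12, Krt32, Krt78, Krt79 and Krt80 as lower. The late cornified envelope family, also a fixed list, had 9 of 20 lower (adjusted p = 0.0426). Changes were rarer among zinc finger genes with the prefix Zfp, 13 of 238 including Zfp750 itself (adjusted p = 1.61e-04), histone genes, 0 of 55 (adjusted p = 0.00739), and Rpl ribosomal protein genes, 0 of 46 (adjusted p = 0.0270). Under the 4 other scalings 11 to 18 Zfp genes, 8 or 9 keratins and 8 or 9 Lce genes were called, and Rpl genes had 2 lower once the libraries were rescaled to a common sum. The Skint genes, of a family tied to epidermal T cells, had 1 of 11 higher and 5 lower and did not pass (adjusted p = 0.0628).

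The stress genes were higher in knockouts 1 and 2, with scores of 6.29 and 6.01, than in knockouts 3 and 4, with 5.07 and 4.41, where the wild types had 4.23 to 4.94. Knockouts 3 and 4 carry title code 44, and the knockout effect may differ between that code and codes 11 and 14. Knockouts 1 and 2 also share KO1 in their titles, so the code and this shared name cannot be told apart here. In limma's interaction test 0 genes passed an adjusted p of 0.05, while 1771 had an unadjusted p under 0.05. The interaction of the stress score was -1.21 ± 0.51 (log2, SE), and camera gave the stress list an adjusted p of 8.60e-06 with codes 11 and 14 alone and 0.839 with code 44 alone. With 2 samples per genotype on each side this stays open.

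Genes beside Zfp750 on chromosome 11 could carry changes of their own through the edited locus or its surroundings. Within 1 Mb, 7 of 29 tested genes had changed, 24.1%, against 121 of 870 elsewhere on the chromosome, 13.9% (two-sided Fisher's exact p = 0.169). The odds ratio was 1.97, with a 95% interval of 0.695 to 4.90, which leaves both no excess and a large one open. The nearest such genes, chosen after their values were seen, were Foxk2 (log2 0.68) and Fn3krp (-0.72). All of the 7 but Fn3krp were higher in the knockouts. The largest rises were those of Dcxr (2.12), Cbr2 (2.01), Slc16a3 (1.73) and Rac3 (1.52).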
